A study of Homo sapiens with 148 samples.

How the data were processed

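Endometrial tissue samples were each measured on 1 Affymetrix whole-genome array, 148 arrays in all. Per the labels' protocols, total RNA was extracted with Trizol, treated with DNase, cleaned on columns, and converted to biotin-labelled cRNA. Per the submitters' processing notes, the values the authors deposited were made with GCRMA, a method that corrects background by probe sequence, quantile-normalizes arrays and summarizes each probe set on the log2 scale. The GCRMA version and whether all arrays were processed together are not given in the sources used here, and the log2 scale was checked from the range of the values. The values covered 54675 probe sets and reached 16.59, and every array had the same minimum. No pair of arrays had identical values, and the highest correlation between 2 arrays was 0.987. Raw scanner data were not used here.

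Groups were taken from the labels: endometriosis, other uterine or pelvic pathology, or no pathology, the stage of endometriosis, and the cycle phase. The comparisons left out 2 LSE arrays, which had only 1 status, and 2 endometriosis arrays with no phase given. The stage comparisons, and the classifiers other than endometriosis against no pathology, also left out 2 endometriosis arrays of unsettled stage, where 1 label gives a stage and another says that none is available. Replicate numbers only name samples.

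The platform annotation listed 1 gene symbol for 41097 probe sets, several for 1801 and none for 11777. Symbols of 41043 probe sets were looked up by gene ID and 0 changed. Only probe sets with 1 symbol named genes, and 59 probe sets of sex-linked genes were left out. Probe sets were kept with a log2 value of at least 4 on at least 6 arrays (30633 kept), and each gene was represented by its probe set with the highest mean over all arrays, which gave 13705 genes. Of these, 878 lie on probe sets whose IDs mark possible cross-hybridization.

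Genes were tested in R 4.3.3 with limma 3.58.1 (lmFit, then eBayes with trend = TRUE and robust = FALSE), two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of adjusted p under 0.05. The fit had 1 mean per status and phase (9 groups, 144 arrays), or per status, stage and phase for stage comparisons (12 groups, 142 arrays). Comparisons over phases weight the 3 phases equally. Differences between cycle steps were tested as interactions. An SE belongs to a fold change, and SDs over phases are means of the SDs within phases. These choices, the gene lists and the alternative settings below were made before the data were examined.

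Named genes were fixed by rule: for each phase-averaged comparison and cycle step the 10 largest log2 changes in each direction past the threshold and up to 4 passing members of each list, and for each comparison within a phase or interaction the 5 largest and up to 2 members. ESR1, PGR, PAEP, MKI67, FOS, CYP19A1, HSD17B2, IGFBP1 and FOXO1 were named whatever their p. The text gives part of these genes.

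The 25 lists were secretory and progesterone, cell cycle, estrogen response, steroid receptor and enzyme, immediate early, inflammatory cytokine, interferon response, matrix remodelling, Wnt pathway, hypoxia and glycolysis, developmental homeobox, DNA repair and ribosomal protein genes, and markers of epithelial, ciliated, stromal, smooth muscle, endothelial, natural killer, T, macrophage, B and plasma, mast and neutrophil, blood and cervical squamous cells. They were tested with camera (preset correlation 0.01), with an estimated correlation and with fry, adjusted over the 25 lists. The mixed p of fry was dropped after a comparison with roast on 1999 rotations, in which it called 5 lists and roast 25 for endometriosis against no pathology, where the directional p called 22 with both.

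Overlap of gene lists against the shared no pathology arrays was set against 100 simulated pairs of unchanged groups and 100 splits of the controls. After the results had been seen, 100 pairs of unchanged groups with the fitted set effects added were drawn as well, and 100 draws of unchanged stages with set effects. Classifiers were diagonal linear discriminants on the 100 genes with the largest absolute t in the training arrays, after subtracting phase means of the training arrays, in 10-fold cross-validation with 5 repeats and 99 shuffles of status within phase, one-sided. Array quality was compared by permutation test with 100000 resamples. Computing used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R with the data.table package, version 1.17.8.

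The labels name no batch. Arrays were divided from 23 control probe sets with a mean log2 value above 4: the deposit order was divided into 6 runs of at least 5 arrays that best separated these values (77.6% of their variation between runs), and the runs were joined by Ward clustering into 3 array sets. A division into 4 sets was tried first and changed to 3 after 3 expression clusters of the arrays had been seen, which hold 26 of 26 arrays of set 1, 75 of 79 of set 2 and 43 of 43 of set 3. The array sets, the deposit runs, the comparisons within sets, and the fits without the 1 tested array whose GAPDH 3-prime to 5-prime ratio was over 3 were thus chosen after seeing the data. A set entered a limma comparison only in phases where it held at least 2 arrays per group.

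The alternative settings were no low value filter (19740 genes), a filter at 6 (12036 genes), the mean over a gene's probe sets, quantile normalization applied again, technical covariates (the first 2 principal components of the spike-in controls and the 3-prime minus 5-prime differences of GAPDH and ACTB), 3 hidden factors from the residuals, array weights, a fold change threshold, leaving out 3 arrays whose title numbers lie outside their group's run, so that their labels are in doubt, fitting only the groups compared, robust eBayes, an additive model, and the stage given in the characteristic of the 2 arrays. Another array, of minimal/mild PE, also has a title number outside its group's run and was not left out.

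The tests were tried on simulated data in which each gene varied independently of the others. False calls among correlated genes, also by camera on lists, were therefore not measured. For endometriosis against no pathology on 13705 genes with 200 changed, limma recovered 84.5% of log2 changes of 1 and 99% of changes of 2, with 2.3% and 5.7% of calls false. For the ESE against PE step in no pathology it recovered 29% and 84.5%. With set effects but no status effect simulated, 10046 genes were called for endometriosis against no pathology without the block and 0 with it, 10052 for other pathology against no pathology and 1601 for stage without it, and 0 for endometriosis against other pathology with or without it. With the block, changes of 1 were recovered at 69%, 51%, 84% and 71% for endometriosis and other pathology against no pathology, endometriosis against other pathology, and stage. A list raised by 1 was the 1 list called among 25. With no difference the classifier's mean area was 0.472 over 20 draws (0.355 to 0.609).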

Results

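Endometrial tissue was profiled on 148 Affymetrix gene expression arrays, 1 array per sample. Endometrium is the inner lining of the uterus, which grows in the proliferative phase (PE) and is remodelled by progesterone in the early (ESE), mid (MSE) and late secretory (LSE) phases. The labels put each sample in 1 of 3 status groups: endometriosis, in which endometrium-like tissue grows outside the uterus, with 77 arrays; another uterine or pelvic pathology without endometriosis, with 37 arrays; and no such pathology, with 34 arrays. Endometriosis was staged as minimal/mild (27 arrays) or moderate/severe (48 arrays). The comparisons used the 144 arrays with a stated PE, ESE or MSE phase: 29, 18 and 28 for endometriosis, 20, 6 and 8 for no pathology, and 15, 6 and 14 for other pathology. The series title names classification of disease and of stage, so the questions were which genes differ by status, by stage and along the cycle, and how well expression separates the groups. After filtering, 13705 genes were tested. The design text counts as many donors as arrays, so each array was taken as 1 donor, and the number of arrays limits the precision of every comparison.

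Arrays had a median log2 value of 3.05 ± 0.07 (SD, n = 148) and 56.9% ± 0.713 of probe sets under 4. The interquartile range ran from 3.77 to 4.93, and array set, defined below, accounted for 46.3% of its spread and 49.8% of that of the percent under 4 (permutation test, p = 1e-05 each). All arrays shared the same lowest value, held by 26.2% to 33.4% of probe sets. Gene expression fell into 3 array sets, which were found from 23 control probe sets and the deposit order; that there are 3 was chosen after 3 clusters of expression had been seen. The first principal component of expression held 40.2% of the variance, and array set accounted for 76.5% of it against 32.4% for status. The second component held 14.4%, of which cycle phase accounted for 71.9%. Signal from ribosomal RNA control probe sets averaged 7.63 ± 1.49 in set 1 (n = 26), 13.0 ± 0.353 in set 2 (n = 79) and 12.1 ± 0.665 in set 3 (n = 43), and array set accounted for 87.3% of its spread. These 5 probe sets are among the 23 that defined the sets, so a difference between sets was built in and was not tested. Over the 9 groups of status and phase, all 7 quality measures differed (adjusted p from 2.33e-05 to 0.00846 by permutation test). Status and array set overlapped unevenly: of the tested arrays, endometriosis had 19 in set 1, 48 in set 2 and 8 in set 3, no pathology had 7, 0 and 27, and other pathology had 0, 31 and 4. Moderate/severe endometriosis had 19, 23 and 5 arrays in the 3 sets and minimal/mild had 0, 23 and 3.

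Arrays of the same status also differed between sets. Moderate/severe endometriosis arrays of set 1 (n = 19) and set 2 (n = 23) differed in 9253 genes, 67.5% of those tested. No pathology arrays of set 1 (n = 7) and set 3 (n = 21) differed in 7402 genes. The sets were themselves made of 6 runs of the deposit order, of which 5 held a single status, and no pathology PE arrays of 2 runs within set 3 (n = 8 and 9) differed in 4416 genes. Within sets 1 and 2 status coincided with the deposit run, and in set 3 15 of 27 no pathology arrays lay in a run without endometriosis, so comparisons of status within a set are also comparisons of runs, wholly or in part. Each comparison is therefore given without an array term, with the set as a block and within sets.

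From PE to ESE in endometriosis, 16 of 37 tested genes of the secretory and progesterone list rose and 1 fell, with the same numbers adjusted over the list alone (camera adjusted p = 0.00197; adjusted p = 0.994 with an estimated correlation). Among all genes STEAP4, a metalloreductase outside that list, rose by 5.76 ± 0.58 on the log2 scale (SE, 54.1-fold, adjusted p = 7.76e-14), from 4.22 ± 2.43 in PE (SD, n = 29) to 9.98 ± 2.49 in ESE (SD, n = 18). HSD17B2, which converts estradiol to the weaker estrone, rose by 4.97 ± 0.65 (adjusted p = 2.1e-09), and XDH, the xanthine dehydrogenase of purine breakdown, by 5.66 ± 0.82. FKBP5, a glucocorticoid and progesterone target, rose by 4.16 ± 0.44. DKK1, a secreted inhibitor of Wnt signalling, rose by 4.09 ± 0.58, and SULT1E1, which sulfates and so inactivates estrogens, by 3.18 ± 0.46. The hedgehog ligand IHH fell by 3.54 ± 0.58 and the matrix metalloproteinase MMP11 by 3.03 ± 0.51. The steroid receptors ESR1 (0.22 ± 0.23, adjusted p = 0.433) and PGR (-0.20 ± 0.34, adjusted p = 0.642), the proliferation marker MKI67 (0.55 ± 0.30, adjusted p = 0.11) and FOS (-1.01 ± 0.78, adjusted p = 0.267) did not pass.

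In all, 7000 genes changed over this step, 3848 up and 3152 down, and 6488 did with the array set as a block. The fold changes with and without the block correlated at 0.97 across genes, which are not independent replicates. Within sets 1, 2 and 3 the counts were 1009 (5 ESE and 5 PE arrays), 6834 (10 and 21) and 276 (3 and 3). IHH differed by set, at -0.20 in set 1 and -4.04 in set 2, and FOXO1, a transcription factor of decidualization, rose by 1.52 ± 0.35 overall (adjusted p = 0.000283) but stood at -0.88 in set 1 (adjusted p = 0.159). PAEP, which encodes the secretory-phase glycoprotein glycodelin, stood at -0.82 ± 0.95 overall (adjusted p = 0.475) and fell by 5.26 in set 1 (adjusted p = 0.0022). Of 21 steroid receptor and enzyme genes, 10 rose and 3 fell, and 11 and 3 did adjusted over the list alone (camera adjusted p = 0.0993; fry adjusted p = 6.51e-07; adjusted p = 0.994 with an estimated correlation).

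In the no pathology group the same step was measured on 6 ESE and 20 PE arrays. HSD17B2 rose by 6.51 ± 1.01 (adjusted p = 3.43e-06), from 3.81 ± 2.09 to 10.3 ± 1.6 (SD), and STEAP4 by 6.50 ± 0.91. LEFTY1, a secreted antagonist of nodal signalling, rose by 5.90 ± 1.01, the amino acid transporter subunit SLC3A1 by 5.65 ± 0.84 and DKK1 by 5.38 ± 0.91. Matrilysin, encoded by MMP7, fell by 3.91 ± 1.06 (adjusted p = 0.02), the transporter SLC47A1 by 3.23 ± 0.84 and the transcription factor MYCN by 2.81 ± 0.69. PDZK1 was at the lowest value on all 6 ESE arrays and at 5.06 ± 2.27 in PE (adjusted p = 0.00952). In total 362 genes changed, 288 up and 74 down, 566 with the set as a block and 806 within set 3 (6 and 17 arrays); set 1 held no ESE array of this group and set 2 none at all. With quantile normalization applied again, 222 rose and 121 fell. Secretory list genes rose in 7 of 37 cases, 10 adjusted over the list alone (camera adjusted p = 7.48e-07; adjusted p = 0.309 with an estimated correlation). Ciliated cell markers rose in 2 of 19 cases, 6 adjusted over the list alone, with a median of 0.92 (camera adjusted p = 1.15e-06; adjusted p = 0.309 with an estimated correlation). Among 28 matrix remodelling genes, 2 fell, 4 adjusted over the list alone (camera adjusted p = 0.000195; adjusted p = 0.309 with an estimated correlation).

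From ESE to MSE in endometriosis (18 and 28 arrays), the window in which the lining becomes able to receive an embryo, genes of several secreted proteins rose. GPX3, a secreted glutathione peroxidase, rose by 6.94 ± 0.72 (123-fold, adjusted p = 4.16e-14), from 7.81 ± 3.59 to 14.8 ± 1.48 (SD). PAEP rose by 6.44 ± 0.96 (adjusted p = 3.11e-08), the complement regulator C4BPA by 5.96 ± 0.60 and the chemokine CXCL14 by 5.76 ± 0.70. COMP, a cartilage matrix protein, rose by 6.80 ± 0.62, and IGFBP1, a marker of decidualized stroma, by 3.91 ± 0.77. The lymphocyte protease genes CTSW and GZMB (granzyme B) rose by 3.18 ± 0.58 and 2.57 ± 0.59. The metalloproteinase MMP26 fell by 6.39 ± 0.97 (adjusted p = 4.88e-08), PKHD1L1 fell by 6.17 ± 0.69 and the peptide transporter SLC15A2 by 5.90 ± 0.60, while SLC15A1, of the same family, rose by 5.90 ± 0.49. ESR1 fell by 1.60 ± 0.24, PGR by 1.70 ± 0.35 and MKI67 by 0.86 ± 0.30 (adjusted p = 0.0215).

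This step changed 4051 genes in endometriosis, 1467 up and 2584 down, and 5075 with the set as a block, of which 4010 were the same genes in the same direction. Within sets 1, 2 and 3 the counts were 3528 (9 MSE and 5 ESE arrays), 3092 (17 and 10) and 193 (2 and 3). MKI67 differed by set: it fell by 3.08 in set 1 (adjusted p = 1.69e-05) and stood at -0.18 in set 2 and 0.64 in set 3. The median of all genes shifted by -0.11, and with quantile normalization applied again the median was -0.01 and 1996 genes rose while 2092 fell. Of the secretory list, 32 of 37 genes rose and 2 fell, with the same numbers adjusted over the list alone, and this call held with an estimated correlation (adjusted p = 0.000927). Of 38 cell cycle genes, 31 fell, 34 adjusted over the list alone (camera adjusted p = 3.4e-08; adjusted p = 0.556 with an estimated correlation). Natural killer cell markers rose in 11 of 14 cases, 13 adjusted over the list alone (camera adjusted p = 2.42e-08; adjusted p = 0.364 with an estimated correlation). Immediate early genes rose in 11 of 29 cases and fell in 1, smooth muscle markers rose in 8 of 19 and endothelial markers in 5 of 18; adjusted over the list alone these were 12 and 1, 9, and 5. The camera adjusted p-values were 1.67e-05, 2.08e-05 and 0.00308, against an adjusted p = 0.556, 0.422 and 0.556 with an estimated correlation. Wnt pathway genes fell in 10 of 25 cases and rose in 2, with the same numbers adjusted over the list alone (camera adjusted p = 0.0403; adjusted p = 0.556 with an estimated correlation).

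In the no pathology group (6 ESE and 8 MSE arrays) C2CD4A rose by 6.68 ± 1.15 (adjusted p = 2.35e-05), GPX3 by 5.87 ± 1.29 (adjusted p = 0.000598), PAEP by 5.75 ± 1.72 (adjusted p = 0.013) and CXCL14 by 4.89 ± 1.25. FOXO1 rose by 2.58 ± 0.63 (adjusted p = 0.00197). The neuropeptide precursor PENK fell by 5.51 ± 1.49, the stromal matrix protein periostin, POSTN, fell by 5.32 ± 1.08, OLFM1 by 4.92 ± 0.91 and endothelin 3, EDN3, by 4.79 ± 0.82. MKI67 (-1.30 ± 0.54, adjusted p = 0.0885) and IGFBP1 (3.43 ± 1.38, adjusted p = 0.0756) did not pass, and did with the set as a block (adjusted p = 0.00268 and 0.025). In total 2084 genes changed, 406 up and 1678 down, 1586 with the block, 570 with the deposit run as a block and 1023 within set 3 (4 and 6 arrays). The median of all genes shifted by -0.30, and with quantile normalization applied again 729 genes rose and 810 fell. Of 37 secretory list genes 26 rose, 28 adjusted over the list alone, which held with an estimated correlation (adjusted p = 0.00246). Cell cycle genes fell in 34 of 38 cases, 37 adjusted over the list alone (camera adjusted p = 1.57e-21; adjusted p = 0.32 with an estimated correlation). Ciliated cell markers fell in 7 of 19 cases, 8 adjusted over the list alone (camera adjusted p = 0.00338; adjusted p = 0.637 with an estimated correlation), and natural killer markers rose in 2 of 14, the same adjusted over the list alone (camera adjusted p = 1.28e-05; adjusted p = 0.498 with an estimated correlation).

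**Figure D1:**
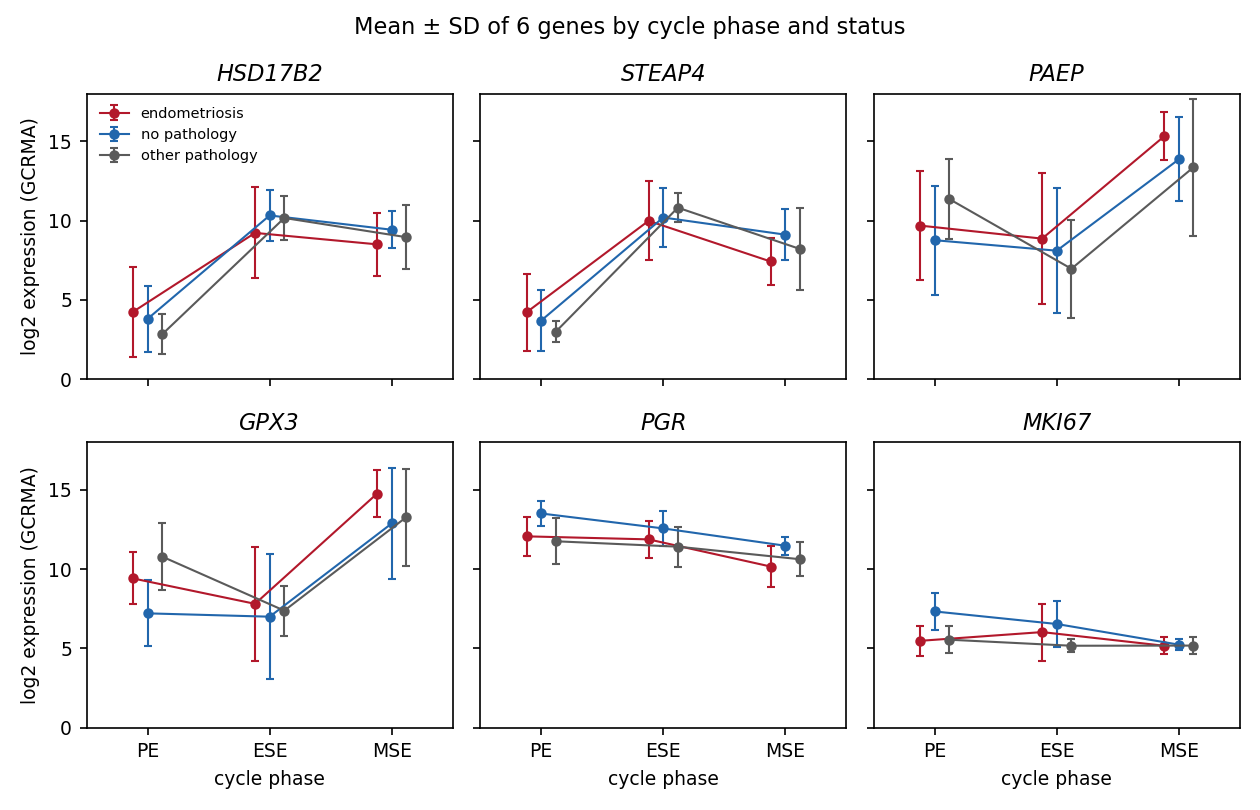
Mean log2 expression with SD bars of 6 genes in PE, ESE and MSE for endometriosis (29, 18 and 28 arrays), no pathology (20, 6 and 8) and other pathology (15, 6 and 14). In endometriosis HSD17B2 went from 4.25 in PE to 9.22 in ESE, and GPX3 from 7.81 in ESE to 14.8 in MSE.

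Whether these steps differed between endometriosis and no pathology was tested by interaction. For PE to ESE 3 genes passed: MAP3K19 (-1.49 ± 0.32, adjusted p = 0.0352), a kinase; IL18R1 (-1.28 ± 0.27, adjusted p = 0.0253), the interleukin 18 receptor; and CCDC81 (-1.15 ± 0.23, adjusted p = 0.0181), a coiled-coil protein. For ESE to MSE 35 genes passed, 34 with the more positive change in endometriosis, among them the kinase PAK5 (2.79 ± 0.59, adjusted p = 0.0112), the actin-binding protein ERMN (2.49 ± 0.62), NETO2 (2.48 ± 0.59), WDR76 (2.41 ± 0.58) and the centromere protein CENPH (2.33 ± 0.55), while FAM185A was at -2.56 ± 0.64 (adjusted p = 0.0448). With the set as a block 9 and 19 genes passed and with the deposit run as a block 1 and 1. These single genes, ARMH4 and RBM20, are named after their values were seen. Leaving out 3 arrays whose title numbers lie outside their group's run, which puts their labels in doubt, gave 3 and 14. With quantile normalization applied again limma called 0 genes (1600 at an unadjusted p under 0.05) and 5, and within set 3 it called 0 (773 at an unadjusted p under 0.05) and 2. No ciliated cell marker or cell cycle gene passed over all genes. Ciliated cell markers had a median difference of -0.92 over PE to ESE (0 of 19 passing, 2 lower adjusted over the list alone; camera adjusted p = 0.000109; adjusted p = 0.989 with an estimated correlation). Cell cycle genes had a median difference of 1.70 over ESE to MSE (0 of 38 passing, also adjusted over the list alone; camera adjusted p = 4.49e-12; adjusted p = 0.919 with an estimated correlation).

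Endometriosis was then set against no pathology, averaged over the 3 phases (75 and 34 arrays). Of 29 immediate early genes, which cells switch on within minutes of a stimulus, 21 were higher and 1 lower, the same adjusted over the list alone (camera adjusted p = 4.48e-07; adjusted p = 0.739 with an estimated correlation). With the set as a block 16 were higher and 0 lower, 24 and 0 adjusted over the list alone, and the call held with an estimated correlation (adjusted p = 0.0143). FOS was higher by 5.06 ± 0.59 (33.3-fold, adjusted p = 3.79e-12; 9.81 ± 2.85 against 4.75 ± 2.12, SD), FOSB by 4.93 ± 0.63, EGR1 by 3.05 ± 0.39, JUNB by 2.82 ± 0.27 and the mRNA decay factor ZFP36 by 2.57 ± 0.33. With the set as a block FOS was higher by 5.41 ± 0.76 (adjusted p = 1.62e-07), FOSB by 4.79 ± 0.81, EGR1 by 3.17 ± 0.45 and JUNB by 1.95 ± 0.33. Within set 3 (8 and 27 arrays) FOS was higher by 3.79 (adjusted p = 0.00785) and within set 1 (14 and 7) it stood at 7.31 (adjusted p = 0.0631). CTSW was higher by 3.09 ± 0.44 but by 1.31 ± 0.49 with the block (adjusted p = 0.0649). SNTN, a protein of cilia, was lower, at -2.74 ± 0.37 (adjusted p = 4.66e-10) and -1.49 ± 0.45 with the block (adjusted p = 0.0199). The mitotic checkpoint kinase BUB1 was at -1.83 ± 0.30 (block -1.21 ± 0.38, adjusted p = 0.0255) and MKI67 at -0.82 ± 0.23 (adjusted p = 0.000812; block -0.77 ± 0.25, adjusted p = 0.0359).

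Several other genes passed without an array term but not with the set as a block. ZNF23 was at -2.35 ± 0.31 (adjusted p = 1.64e-10) but at -0.15 ± 0.26 with the block and 0.29 within set 3, and TMEM181 at -2.28 ± 0.43 but -0.39 ± 0.35 with the block. PGR was at -1.15 ± 0.26 (adjusted p = 5.11e-05) against -0.35 ± 0.28 (adjusted p = 0.487), ESR1 at -0.52 ± 0.18 (adjusted p = 0.00637) against 0.15 ± 0.19 (adjusted p = 0.701), and CYP19A1, the aromatase that makes estrogens, at 0.39 ± 0.10 (adjusted p = 0.000175) against 0.13 ± 0.12 (adjusted p = 0.533). ESR1 also stood at 0.03 when probe sets of a gene were averaged. FOXO1 was at -0.60 ± 0.27 (adjusted p = 0.0332) and at 0.69 ± 0.28 with the block (adjusted p = 0.091). PAEP (1.04 ± 0.73), HSD17B2 (-0.53 ± 0.50) and IGFBP1 (-0.05 ± 0.58) did not pass.

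Without an array term 11010 genes differed, 4663 higher and 6347 lower, 1353 did with the set as a block and 174 with the deposit run as a block. Of the 11010, 62.6% had the same sign with the set block (82.7%, 84.4% and 69.8% of the genes called in PE, ESE and MSE), where both fits use the same arrays. Of the 1353, 1014 were among the 11010, 710 of them in the same direction and the others in the opposite one, and of the 174, 123 and 105. Within set 1 (PE and MSE only) 40 genes passed and within set 3 2883 did, while set 2 held no array without pathology. Blocks of deposit runs leave this comparison to the only run that held all 3 statuses, with 8 endometriosis, 12 no pathology and 4 other pathology arrays tested. By phase, counts without a term, with the set and with the run as a block were 11165, 2515 and 1167 in PE, 2999, 787 and 31 in ESE, and 4022, 8 and 30 in MSE. Without the 3 arrays of doubtful label the ESE count was 1881 in place of 2999. The median of all genes shifted by -0.19 (-0.25, -0.24 and -0.04 in the 3 phases), and by -0.07 with quantile normalization applied again, which turned the 584 higher and 2415 lower genes of ESE into 1031 and 1148. Cell cycle genes were lower in 30 of 38 cases and higher in 2, the same adjusted over the list alone (camera adjusted p = 0.0229; adjusted p = 0.819 with an estimated correlation), and with the block 17 were lower, 35 adjusted over the list alone (adjusted p = 0.544 with an estimated correlation). In PE alone 32 of them were lower with the block, 37 adjusted over the list alone (camera adjusted p = 1.47e-15; adjusted p = 0.788 with an estimated correlation). DNA repair genes were lower in 17 of 21 cases and higher in 3 (camera adjusted p = 0.0361; adjusted p = 0.739 with an estimated correlation), the same adjusted over the list alone, and none passed with the block.

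**Figure D2:**
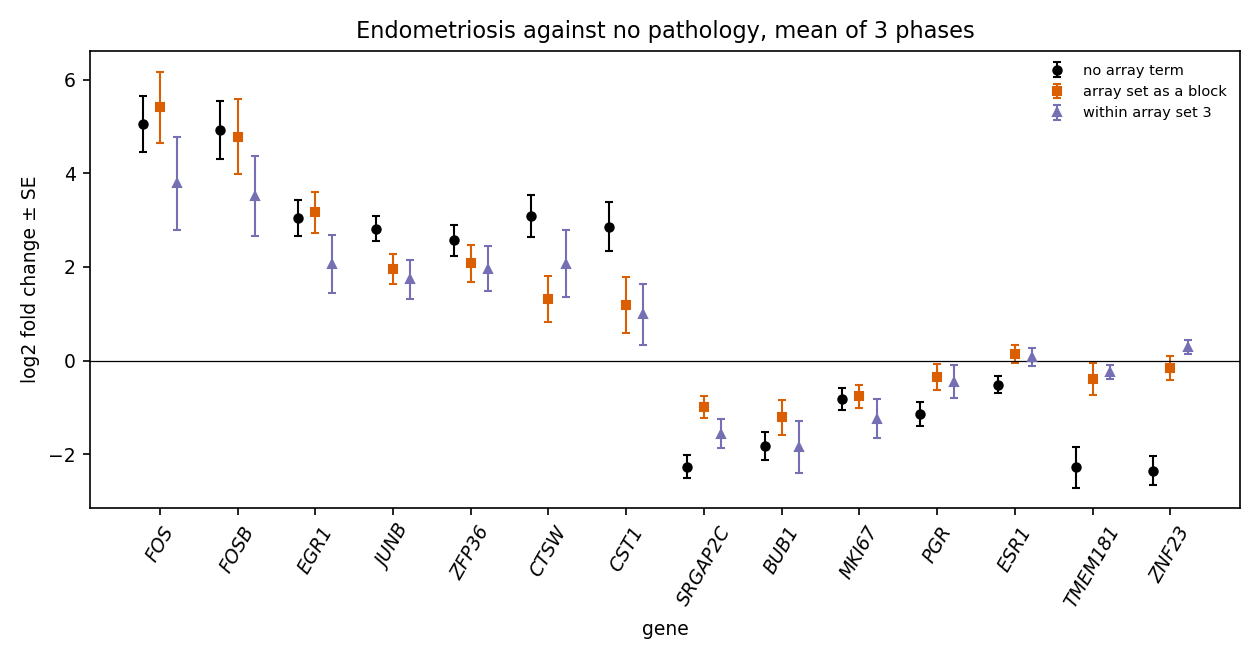
Log2 fold change of endometriosis over no pathology with SE bars for 14 genes, without an array term (75 and 34 arrays), with the array set as a block and within array set 3 (8 and 27 arrays). FOS stays above 3 in all 3 fits, and ZNF23 moves from -2.35 without a term to 0.29 within set 3.

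Other pathology against no pathology (35 and 34 arrays) gave many of the same genes. FOSB was higher by 5.89 ± 0.74 (adjusted p = 4.99e-11), FOS by 5.56 ± 0.70, EGR1 by 3.96 ± 0.46, the nuclear receptor NR4A1 by 3.91 ± 0.50 and ZFP36 by 3.65 ± 0.38, and with the set as a block they were higher by 5.62 ± 0.93, 5.68 ± 0.87, 3.50 ± 0.51, 3.36 ± 0.63 and 2.82 ± 0.45. The smooth muscle genes ACTG2 and CNN1 were higher by 3.14 ± 0.51 and 3.08 ± 0.45 (block 1.87 ± 0.58, adjusted p = 0.0179, and 1.67 ± 0.50, adjusted p = 0.0131). SNTN was at -2.88 ± 0.43 (block -1.45 ± 0.51, adjusted p = 0.0429). PGR was at -1.25 ± 0.31 (adjusted p = 0.00018) but -0.03 ± 0.32 with the block (adjusted p = 0.966), and ESR1 turned from -0.46 ± 0.21 (adjusted p = 0.0397) to 0.46 ± 0.22 (adjusted p = 0.17). FOXO1, at -0.55 ± 0.31 (adjusted p = 0.0975), was higher by 1.07 ± 0.32 with the block (adjusted p = 0.0121).

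The counts were 10347 genes without a term (4774 higher, 5573 lower), 1840 with the set and 65 with the run as a block, and 46% of the 10347 had the same sign with the set block (59.4%, 99.1% and 28.4% of the genes called in PE, ESE and MSE). Of the 1840, 1391 were among the 10347, 686 of them in the same direction and the others in the opposite one, and of the 65, 40 and 34. Only 4 other pathology arrays shared a set with no pathology, and within set 3 the ESE arrays (2 and 6) differed in 1503 genes. By phase the 3 counts were 10393, 1088 and 170 in PE, 3081, 1126 and 17 in ESE and 4479, 13 and 15 in MSE. The ESE count was 1260 without the 1 tested array whose GAPDH 3-prime to 5-prime ratio was over 3. Quantile normalization applied again turned 935 higher and 2146 lower genes in ESE into 1588 and 1596, and 3197 and 1282 in MSE into 2494 and 2584. Immediate early genes were higher in 24 of 29 cases, the same adjusted over the list alone (camera adjusted p = 3.07e-09; adjusted p = 0.871 with an estimated correlation), and with the block in 26, 28 adjusted over the list alone, which held (adjusted p = 0.0213 with an estimated correlation). Smooth muscle markers were higher in 13 of 19 and lower in 2, the same adjusted over the list alone (camera adjusted p = 0.00345; adjusted p = 0.871 with an estimated correlation), and with the block in 7, 10 adjusted over the list alone (adjusted p = 0.372 with an estimated correlation).

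Endometriosis and other pathology shared 9647 genes called in the same direction against the no pathology arrays, 4215 up and 5432 down, and 1 in opposite directions. Independent lists would share 1624 and 2581. Their fold changes correlated at 0.965 across genes with a covariance of 0.823, where simulated unchanged groups against the same controls gave a mean correlation of 0.605, a covariance of 0.0306 and at most 359 shared genes in 100 draws without a set effect. When the fitted set effects were added to unchanged groups, 8710 to 10660 genes were shared, with a mean correlation of 0.977 and a covariance of 0.93, so the overlap without an array term lay within what set effects alone gave. With the controls split, the means were 7979 shared genes, a correlation of 0.92 and a covariance of 0.802. With the set as a block 953 genes were shared, with a covariance of 0.119, where unchanged groups with set effects shared 0 in every draw by limma, with a covariance of at most 0.0808. The correlation with the block was 0.836, inside the 0.44 to 0.927 of these draws. With the run as a block 22 were shared. None of the draws held a difference between deposit runs, so they do not separate status from run for the 953 genes.

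Endometriosis differed less from other pathology (75 and 35 arrays), which lay mostly in the same set. BPIFB1, a secreted protein of mucosal glands, was higher by 2.00 ± 0.56 (adjusted p = 0.031; block 2.41 ± 0.56, adjusted p = 0.0141), with other pathology near the lowest value at 2.44 ± 0.76 (SD). The prostaglandin receptor gene PTGER3 was higher by 1.22 ± 0.35, but by 0.24 ± 0.18 with the block (adjusted p = 0.471). The antisense transcript ZNF143-AS1 was higher by 0.75 ± 0.20 (adjusted p = 0.0238), by 1.15 ± 0.17 with the block (adjusted p = 1.8e-06) and by 1.28 within set 2 (adjusted p = 0.000255). Lower genes were ACTG2 (-1.52 ± 0.42), CEL (-1.51 ± 0.39), NR4A1 (-1.51 ± 0.41), CCN1, a matrix signalling protein (-1.46 ± 0.37), and CNN1 (-1.44 ± 0.36), with adjusted p from 0.0178 to 0.0288, none of which passed with the block. FOS (-0.50 ± 0.57), PGR (0.10 ± 0.25), ESR1 (-0.05 ± 0.17), PAEP (0.73 ± 0.70) and MKI67 (0.26 ± 0.22) did not pass.

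In this comparison 433 genes passed, 55 higher and 378 lower, 115 with the set (37 of them among the 433) and 3 with the run as a block (CYTOR, ZNF684 and LINC01238, named after their values were seen), and 30 within set 2 (48 and 31 arrays, each status in its own deposit run). It was 198 without the 1 array of high GAPDH ratio, and quantile normalization applied again gave 132 higher and 90 lower, where the median of all genes moved from -0.12 to 0.02. In PE 8 genes passed, with CCN1 (-2.32 ± 0.53), the vasoconstrictor precursor EDN1 (-1.96 ± 0.38), ST8SIA2 (-1.69 ± 0.37) and the histone gene H3C2 (1.01 ± 0.23) among them, and 655 with the block. In ESE 12 passed, including MRPS18C (1.14 ± 0.21), ZMYM6 (1.39 ± 0.33) and ART3 (-2.43 ± 0.56), against 49 with the block and 3 without the 1 array of high GAPDH ratio: CYTOR, MRPS18C and LINC00115, named after their values were seen. In MSE 8 passed, including the drug-metabolizing CYP3A5 (2.31 ± 0.45), DLGAP1-AS3 (2.17 ± 0.46), DIPK1C (-1.66 ± 0.36) and the mucin MUC7 (-1.37 ± 0.30), against 12 with the block and, by limma, 0 within set 2 (1200 at an unadjusted p under 0.05) and 0 with the run as a block (913 at an unadjusted p under 0.05). Quantile normalization applied again gave 3 higher and 2 lower genes in PE in place of 1 and 7, 13 and 2 in ESE in place of 9 and 3, and 14 and 2 in MSE in place of 6 and 2. Immediate early genes were lower in 6 of 29 cases, 13 adjusted over the list alone (camera adjusted p = 6.01e-06; adjusted p = 0.416 with an estimated correlation), and smooth muscle markers in 5 of 19, 9 adjusted over the list alone (camera adjusted p = 0.000875; adjusted p = 0.416 with an estimated correlation). With the set as a block 0 members of either list passed over all genes, and 4 and 0 were lower adjusted over the list alone.

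**Figure D3:**
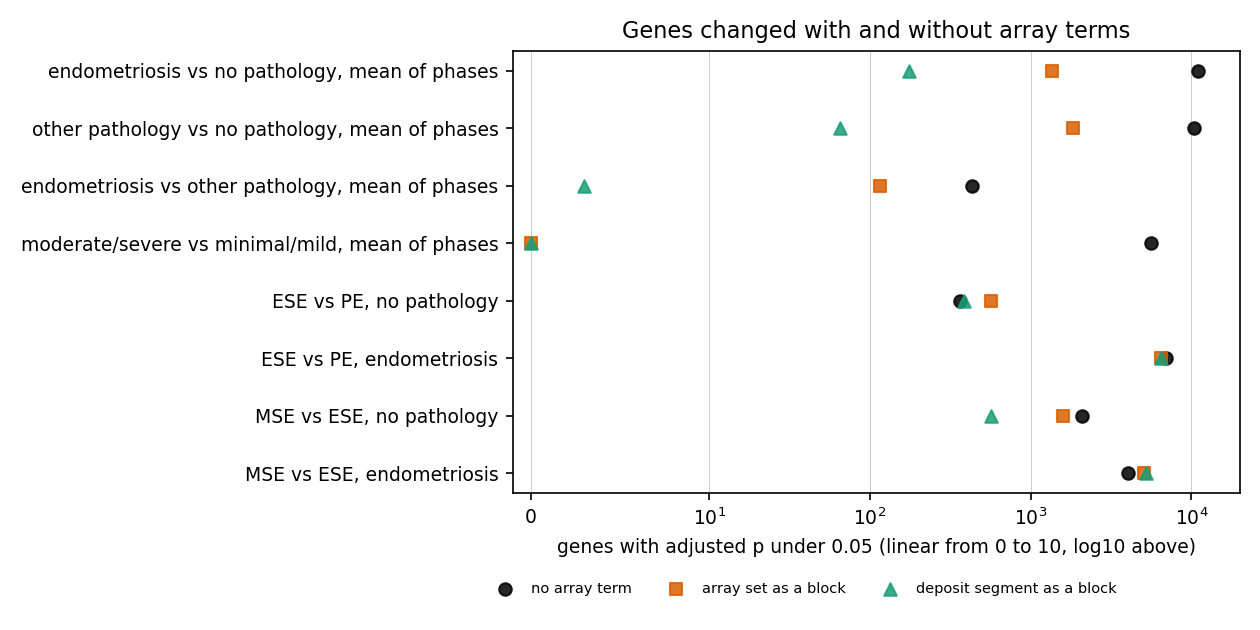
Genes with an adjusted p under 0.05 in 8 comparisons (linear axis from 0 to 10, log10 above) without an array term, with the array set as a block and with the deposit run as a block. Moderate/severe against minimal/mild endometriosis falls from 5611 to 0 genes with either block, while the ESE against PE step in endometriosis stays between 6488 and 7000.

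Moderate/severe was set against minimal/mild endometriosis (47 and 26 arrays). VMP1, an autophagy protein, was higher by 1.91 ± 0.43 (adjusted p = 0.000489), ZNF292 by 1.76 ± 0.40 and FAP, the fibroblast activation protein, by 1.55 ± 0.41. HOXB8, a patterning homeobox gene, was at -2.35 ± 0.44 (adjusted p = 0.00015), MSLN, the mesothelial surface protein mesothelin, at -2.33 ± 0.48 and HES1, a Notch target, at -2.27 ± 0.51. None passed with the set as a block, at 0.53 ± 0.33, 0.05 ± 0.22, 0.66 ± 0.39, -0.32 ± 0.17, -1.71 ± 0.51 and -0.42 ± 0.37 in that order (adjusted p from 0.608 to 0.927). PGR (0.69 ± 0.28), MKI67 (0.86 ± 0.24) and FOXO1 (0.86 ± 0.28) were higher without a term (adjusted p from 0.00342 to 0.0397) and were at 0.03 ± 0.26, 0.28 ± 0.23 and 0.40 ± 0.26 with the block.

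Without a term 5611 genes passed, 1717 higher and 3894 lower, and 3275 and 2880 with quantile normalization applied again. With the set and the run as a block limma called 0, with 1080 and 882 genes at an unadjusted p under 0.05, and within set 2, where both stages had 23 arrays from 1 deposit run, limma called 0, with 432 genes at an unadjusted p under 0.05. Of the 5611, 92.9% had the same sign with the set block, in a fit of the same arrays. With set effects and no stage difference simulated, 1306 to 6015 genes passed without a term in 100 draws (3 draws gave at least 5611), with 36.9% to 93.5% of the same sign. In PE 5725 genes passed and 22 with the block, among them MYCN (-2.77 ± 0.52; block -2.44 ± 0.54, adjusted p = 0.0236) and C16orf89 (-2.67 ± 0.50; block -2.03 ± 0.48, adjusted p = 0.0392). Within set 2 these did not pass, at -2.16 and -1.49 (adjusted p = 1). In MSE 5664 passed and 2 with the block: CATSPERB, a sperm calcium channel subunit (3.31 ± 0.48; block 2.81 ± 0.50, adjusted p = 0.00184), and LOXL1, which crosslinks elastin (-3.31 ± 0.49; block adjusted p = 0.0333). Within set 2 neither passed, at 1.66 (adjusted p = 0.792) and -0.98 (adjusted p = 1). Quantile normalization applied again gave 3263 higher and 2880 lower genes in MSE in place of 2006 and 3658. In ESE, ITGBL1 alone passed (1.63 ± 0.33; block 1.71 ± 0.34, adjusted p = 0.0232). Within set 2 (7 and 3 arrays) it did not, at 1.38 (adjusted p = 0.339), and the 1 gene called there was ALPP (-4.50, adjusted p = 0.0199), named after its value was seen. Further, with the run as a block limma called 0 genes (290 at an unadjusted p under 0.05). Endothelial markers were lower in 12 of 18 cases (camera adjusted p = 0.0386; adjusted p = 0.98 with an estimated correlation), and cell cycle genes were higher in 7 of 38 and lower in 1 (camera adjusted p = 0.00119; adjusted p = 0.98 with an estimated correlation). DNA repair genes were higher in 9 of 21 cases and lower in 2 (camera adjusted p = 0.00791; adjusted p = 0.98 with an estimated correlation). Adjusted over the list alone these counts were 12, 5 and 1, and 9 and 2, and with the block 0 members of these lists passed.

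Each stage was also set against no pathology. Minimal/mild differed in 11121 genes (1041 with the set and 121 with the run as a block) and moderate/severe in 9710 (888 and 96). The moderate/severe genes were 3503 higher and 6207 lower, or 4656 and 5181 with quantile normalization applied again.

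Classifiers of 100 genes, chosen inside each training fold, separated endometriosis from no pathology with an area under the ROC curve in held-out folds of 0.944 ± 0.004 (SD over 5 repeats, 75 and 34 arrays), other pathology from no pathology with 0.963 ± 0.009 (35 and 34), endometriosis from other pathology with 0.744 ± 0.01 (73 and 35, without the 2 arrays of unsettled stage) and moderate/severe from minimal/mild endometriosis with 0.732 ± 0.011 (47 and 26). Each had a one-sided permutation p = 0.01 in 99 shuffles, the smallest they can give. The array set alone, with no gene, gave 0.876, 0.922, 0.566 and 0.648 in the same order. After regression on the technical covariates the areas were 0.8, 0.573, 0.645 and 0.462. Centred per array set, endometriosis against no pathology gave 0.605 (permutation p = 0.08, shuffled mean 0.495) and endometriosis against other pathology 0.665 (permutation p = 0.01). Within sets 1 and 3 endometriosis against no pathology gave 0.898 (19 and 7 arrays) and 0.923 (8 and 27), both with permutation p = 0.01. Classifiers trained outside these sets gave 0.338 and 0.472 in them. All 5 ESE arrays of set 1 were endometriosis, also when shuffled, which limits its area and p. Within set 2 endometriosis against other pathology gave 0.69 (46 and 31 arrays, permutation p = 0.01). In sets 1 and 2 each status had its own deposit run and in set 3 runs and status overlapped in part. The shuffles did not hold the run, so these areas do not separate status from run. The stages, which shared a run within set 2, gave 0.46 there (23 and 23 arrays, permutation p = 0.66), and a stage classifier trained outside set 3 gave 0.733 when tested in it (5 and 3 arrays). In set 3 the 3 minimal/mild arrays were ESE, and 3 and 2 moderate/severe arrays PE and MSE. That area does not separate stage from phase.

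**Figure D4:**
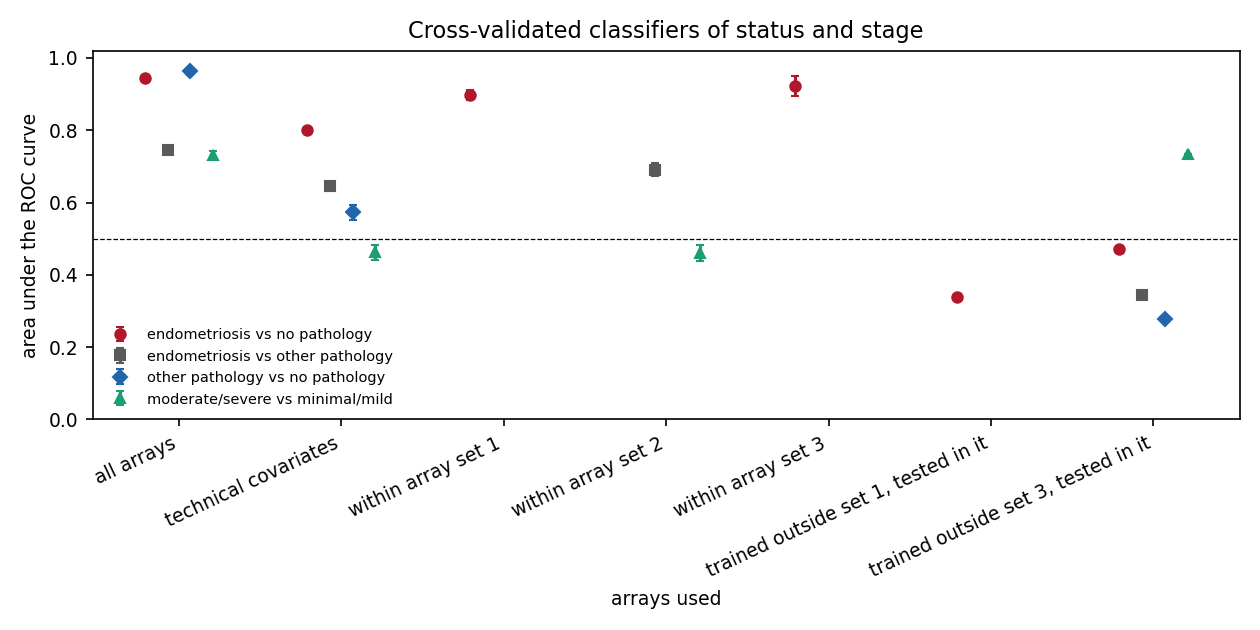
Area under the ROC curve of 4 classifiers for all arrays, after regression on technical covariates, within single array sets, and when trained outside a set and tested in it; bars are the SD over 5 repeats and the dashed line marks 0.5. The stage classifier falls from 0.732 over all arrays to 0.46 within set 2.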

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

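The tests by array set and by deposit run, the simulated set effects, and the shuffles within array sets, were tests chosen after the data had been seen, while the rules for single arrays, the interactions and the shuffles within phase were fixed in advance.

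An array was singled out where its gap to the nearest other, as a share of its group's range, passed Dixon's limit. In groups of 4 to 10 arrays, 8 of 40 quality values and 10 of 61 gene values passed, and chance flags about 1 in 20 groups. The 61 count a gene and group for each comparison that names the gene, while the 10 count each once. The 10 of 61 is therefore not a share to set against chance. Among no pathology ESE arrays, the share was 0.651 for the median log2 value and 0.718 for the percent of probe sets under 4. For the 3-prime minus 5-prime differences of GAPDH and ACTB it was 0.555 and 0.668 in no pathology MSE, 0.818 and 0.717 in other pathology ESE, and 0.682 and 0.555 in minimal/mild MSE. Among named genes it was 0.638 for DKK1, 0.706 for ESR1, 0.998 for IGFBP1, 0.715 for GPX3 and 0.783 for PKHD1L1 in no pathology ESE, 0.587 for MKI67, 0.668 for FOS and 0.81 for CYP19A1 in no pathology MSE, and 0.7 for CATSPERB and 0.52 for TRPM8 in minimal/mild MSE.

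The cycle steps differed between endometriosis and no pathology by interaction in 3 genes from PE to ESE (MAP3K19 -1.49, IL18R1 -1.28 and CCDC81 -1.15) and in 35 from ESE to MSE (among them PAK5 2.79, ERMN 2.49, NETO2 2.48, WDR76 2.41, CENPH 2.33 and FAM185A -2.56). Over 100 splits of the labels within phase, the real one included, 10 gave at least 3 genes and the highest other gave 162, so chance cannot be excluded for the first. For the second 4 gave at least 35 and the highest other gave 183, so chance within phase can be excluded at the 0.05 level, although a split that calls several times the real count points to a structure of the samples. Array set was not held in these shuffles: it accounted for 57.8% and 40% of the real splits and at most 4% and 2.2% of the others. The count of 35 became 14 without the 3 arrays whose title numbers put their labels in doubt, 19 with the set as a block, 1 with the run as a block and 5 with quantile normalization applied again, so this exclusion does not reach array set or run.

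Endometriosis against no pathology gave 11010 genes without an array term and 1353 with the array set as a block. Of these, 1014 were among the 11010 and 710 in the same direction. Arrays of the same status differed by set in up to 9253 genes. Set effects simulated without a status difference gave 9526 to 11370 genes, so array set alone can reach the count. Against it as the cause of the 1353, labels shuffled within phase and array set gave at most 128 genes in the other splits. Of the 11010, 62.6% kept their sign with the block, a share not simulated for set effects. A lost call alone does not tell array set from status, since set 2 has 48 endometriosis arrays but none without pathology. A biological difference by status and a difference between deposit runs stay open. The run as a block gave 174 genes, 123 of them among the 11010 and 105 in the same direction.

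Other pathology against no pathology gave 10347 genes and 1840 with the array set as a block, of which 1391 were among the 10347 but only 686 in the same direction. A difference between array sets is a candidate explanation for much of this count. Against it as the cause of the 1840, labels shuffled within phase and array set gave at most 17 genes in the other splits. Only 4 other pathology arrays share a set with no pathology, and the others enter through endometriosis, which takes the set shift to be alike in every status. The run as a block gave 65 genes, 40 of them among the 10347 and 34 in the same direction, so a difference between deposit runs stays open beside a biological difference.

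Moderate/severe against minimal/mild endometriosis gave 5611 genes, and limma called 0 with the array set as a block (1080 at an unadjusted p under 0.05). All 19 staged arrays of set 1 were moderate/severe, and a difference between array sets is a candidate explanation for the count. Set effects simulated without a stage difference gave 1306 to 6015 genes, with 3 of 100 draws at 5611 or more, so they can reach the count but mostly gave fewer. With the block, simulated log2 changes of 1 in 200 genes were recovered at 71%, but the simulated genes varied independently of each other. Shuffles of the staged arrays within phase and array set called up to 7028 genes, which points to genes that vary together. The simulation therefore does not decide whether a loss of power gave the 0. In single phases 22 genes passed with the block in PE and 2 in MSE, where chance was not excluded. A biological difference by stage stays open.

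Each count was also set against 100 splits of the labels within phase, the real one included. Chance can be excluded, with 1 split as large, for endometriosis against no pathology (11010 genes, highest other 6440; 11165 and 4395 in PE, 4022 and 789 in MSE, and 2999 in ESE, where every other split gave fewer). The same holds for other pathology against no pathology (10347 and 2341; 10393 and 6702 in PE, 3081 and 1258 in ESE, 4479 and 476 in MSE), minimal/mild against no pathology (11121 and 27) and moderate/severe against no pathology (9710 and 3030). For stage it can be excluded over the phases (5611 and 4611), in PE with 2 splits as large (5725 and 7435) and in MSE (5664 and 5358), but not in ESE with 48 (1 and 759). For endometriosis against other pathology it can be excluded over the phases with 2 as large (433 and 1550), but not in PE with 12 (8 and 7000), ESE with 11 (12 and 3338) or MSE with 10 (8 and 3063). With the 2 phases shuffled within a status, it can be excluded for ESE against PE with 2 as large (no pathology 362 and 489, endometriosis 7000 and 8263) and for MSE against ESE with 1 (2084 and 1527, 4051 and 2129). Shuffles that call as many as 8263 genes point to a structure of the samples. Array set accounted for 51.8% of the real split of endometriosis and no pathology (highest other split 11.9%), 79.8% for other pathology and no pathology (9.6%), 9.9% for endometriosis and other pathology (7%) and 20.1% for stage (5.4%), so shuffles within phase leave a set effect in the real count.

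With the labels of all 3 statuses, or of the 2 stages, shuffled within phase and array set, and the set as a block, chance can be excluded with 1 split as large for endometriosis against no pathology (1353, highest other 128; 2515 and 489 in PE, 787 and 497 in ESE) but not in MSE with 11 (8 and 285). For other pathology against no pathology it can be excluded over the phases (1840 and 17) and in ESE (1126 and 128), with 1 split as large each. The splits of the 2 groups possible are too few for a share under 0.05 in PE (1088 and 3218, 9 as large) and MSE (13 and 397, 11 as large). For endometriosis against other pathology it can be excluded over the phases with 3 as large (115 and 2463), but not in PE with 7 (655 and 4453), ESE with 6 (49 and 669) or MSE with 12 (12 and 258). For stage over the phases the shuffles say nothing about chance, since limma called 0 (1080 at an unadjusted p under 0.05) and any split is then as large, 100 of 100 (highest other 7028). Chance cannot be excluded for stage in PE with 32 (22 and 4887), ESE with 76 (1 and 3045) or MSE with 55 (2 and 3325). Shuffled counts up to 7028 point to a structure of the samples within the sets.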

How the results depend on the processing

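The array sets, deposit runs, fits within sets, fits without the array of high GAPDH ratio, and the classifiers centred by set or trained outside a set were tests chosen after results had been seen; the other alternatives were fixed in advance. No paired analysis was possible because replicate numbers only name samples. In this part E is endometriosis, N no pathology, O other pathology, S moderate/severe and M minimal/mild endometriosis, a count with no phase is the mean of the phases at hand, and a limma count of 0 is given with the number of genes at an unadjusted p under 0.05. Counts not printed here lay within 1.5 times those of the report, and gene values that ceased or began to pass are given as numbers only. Unless stated, the cause of a change was not tested.

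The counts of the report were E against N 11010 (11165, 2999 and 4022 in PE, ESE and MSE), O against N 10347 (10393, 3081 and 4479 in PE, ESE and MSE), E against O 433 (8, 12 and 8 in PE, ESE and MSE), S against M 5611 (5725, 1 and 5664 in PE, ESE and MSE), M against N 11121 and S against N 9710. Cycle counts were the ESE against PE step in N 362, the ESE against PE step in E 7000, the ESE against PE interaction 3, the MSE against ESE step in N 2084, the MSE against ESE step in E 4051, the MSE against ESE interaction 35 and genes shared by E and O 9647.

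Of the 184 gene values of the text, alternatives fixed in advance gave 1936 values on the same side of the threshold, 136 in the same direction that no longer passed (58 results), 35 that newly passed and 4 of opposite sign. Alternatives added later gave 745, 270 (110 results), 7 and 32 (16 results). Of the summaries, 89 moved and 1 reversed under alternatives fixed in advance, against 96 and 7 for those added later. Of the gene list values, 93 fixed in advance stayed, 17 became and 52 ceased to be calls, against 43, 7 and 3 with the set as a block and 1 reversed. Robust eBayes and the stage from the characteristic moved no count by over 1.5 times. Arrays with signal near the shared lowest value limit changes there: 26.2% to 33.4% of probe sets sat at it, and a fold change against them is bounded by it.

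With the array set as a block the counts were E against N 1353 (2515, 787 and 8 in PE, ESE and MSE), O against N 1840 (1088, 1126 and 13 in PE, ESE and MSE), E against O 115 (655 and 49 in PE and ESE), S against M 0 with 1080 unadjusted (22 and 2 in PE and MSE), M against N 1041 and S against N 888. Here the cycle and overlap counts were the ESE against PE step in N 566, the ESE against PE interaction 9, the MSE against ESE interaction 19 and genes shared by E and O 953. ESR1 turned to 0.15 in E against N and 0.46 in O against N, FOXO1 to 0.69 and 1.07, and CYP19A1 to -0.01 in O against N. Endothelial markers in E against O went from a median of -0.34 (camera adjusted p = 0.0344) to 0.01 (camera adjusted p = 0.74).

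With the deposit run as a block they were E against N 174 (1167, 31 and 30 in PE, ESE and MSE), O against N 65 (170, 17 and 15 in PE, ESE and MSE), E against O 3 (1 in PE, 4 in ESE and 0 with 913 unadjusted in MSE), S against M 0 with 882 unadjusted (12 in PE, 0 with 290 unadjusted in ESE and 1 in MSE), M against N 121 and S against N 96. Cycle and overlap counts were then the ESE against PE interaction 1, the MSE against ESE step in N 570, the MSE against ESE interaction 1 and genes shared by E and O 22. In E against N, ZNF23 turned to 0.29 and FOXO1 to 1.28. In O against N, ESR1 turned to 0.37 and PGR to 0.26. PTGER3 turned to -0.14 in E against O and ZNF292 to -0.06 in S against M.

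Leaving out the 1 other pathology ESE array of high GAPDH ratio gave O against N 1260 in ESE and E against O 198 (3 in ESE). With the set block as well the counts were E against N 1319 (2587, 767 and 11 in PE, ESE and MSE), O against N 1850 (1062, 924 and 13 in PE, ESE and MSE), E against O 70 (618 in PE), S against M 0 with 1091 unadjusted (22 and 2 in PE and MSE), M against N 1019 and S against N 867. The cycle counts were then the ESE against PE step in N 568, the ESE against PE interaction 8 and the MSE against ESE interaction 18. ESR1 stood at 0.15 in E against N and 0.46 in O against N, FOXO1 at 0.68 and 1.09, and in O against N PGR at 0 and CYP19A1 at -0.01.

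Within set 1 (no M, O or ESE N arrays, so E and S against N hold PE and MSE only) the counts were E against N 40 (47 and 2 in PE and MSE), S against N 40 and the ESE against PE step in E 1009. CYP19A1 turned to 0.02 and FOXO1 to -0.88 over the ESE against PE step in E, and in E against N CST1 turned to -0.77 and FOXO1 to 0.77. The 2 MSE genes, THRB and ATN1, are named after their values were seen. Within set 2 (no N arrays) they were E against O 30 (1443 in PE, 139 in ESE and 0 with 1200 unadjusted in MSE) and S against M 0 with 432 unadjusted (0 with 399 unadjusted in PE and 2 in MSE). In S against M, ZNF292 turned to -0.09, TMEM181 to -0.14 and PGR to -0.14. The 2 MSE genes were STAT4 and LILRP2, also named after their values were seen. Within set 3, where O against N (2 and 6 arrays), E against O (3 and 2) and M against N (3 and 6) hold ESE only and S against N (5 and 21) PE and MSE only, they were E against N 2883 (1760, 912 and 13 in PE, ESE and MSE), O against N 1503 (1503 in ESE), E against O 4 (4 in ESE), M against N 912 and S against N 915. The cycle counts there were the ESE against PE step in N 806, the ESE against PE step in E 276, the ESE against PE interaction 0 with 773 unadjusted, the MSE against ESE step in N 1023, the MSE against ESE step in E 193 and the MSE against ESE interaction 2. MKI67 turned to 0.64 over the MSE against ESE step in E. In E against N, ZNF23 turned to 0.29, ESR1 to 0.08 and FOXO1 to 0.96. On these ESE arrays alone, against means of 3 phases in the report, ESR1 stood at 0.39 and PGR at 0.14 in O against N, and PTGER3 at -0.18 and SUZ12P1 at -0.05 in E against O.

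With technical covariates the counts were E against N 461 and 11 in ESE and MSE, O against N 4850 (135 and 23 in ESE and MSE), E against O 3 (1 and 3 in PE and ESE), S against M 1 (3411 and 1935 in PE and MSE) and S against N 5170. Of the cycle counts, this moved the ESE against PE step in E 4052. With 3 hidden factors they were E against N 7471 and 8473 in ESE and MSE, O against N 7863 and 7691 in ESE and MSE, E against O 4667 (3493, 1595 and 3887 in PE, ESE and MSE) and S against M 0 with 1032 unadjusted (18 and 2 in PE and MSE). Cycle counts were the ESE against PE step in N 1894, the ESE against PE interaction 4669, the MSE against ESE step in N 5873, the MSE against ESE step in E 7634 and the MSE against ESE interaction 1814. TMEM181 turned to -0.25 and PGR to -0.14 in S against M. These factors come from the residuals of the fit of 9 groups, so its fold changes stay as they are and the spread falls, while in the stage comparisons they take up part of the difference. With array weights the counts were E against N 5302 in ESE, O against N 8869 and 7919 in ESE and MSE, E against O 3600 (885, 3872 and 684 in PE, ESE and MSE) and S against M 3379, 768 and 9090 in PE, ESE and MSE. Cycle counts with weights were the ESE against PE step in N 2241, the ESE against PE interaction 7447, the MSE against ESE step in N 7324 and the MSE against ESE interaction 3550.

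Fitting only the groups compared gave E against N 1514 in MSE, E against O 152 (0 with 1445 unadjusted in PE, 0 with 611 unadjusted in ESE and 0 with 1942 unadjusted in MSE) and S against M 1 in PE and 0 with 491 unadjusted in ESE. For the cycle it gave the ESE against PE step in N 1080, the ESE against PE interaction 1, the MSE against ESE step in N 3540 and the MSE against ESE interaction 94. Without a filter the counts were E against O 244 (5 and 101 in PE and ESE), S against M 16 in ESE, the ESE against PE interaction 20 and the MSE against ESE interaction 80. With a filter at 6 they were E against O 3 and 6 in PE and ESE, S against M 0 with 658 unadjusted in ESE, the ESE against PE interaction 0 with 1462 unadjusted and the MSE against ESE interaction 3. With the mean over probe sets they were E against O 239 (19, 6 and 30 in PE, ESE and MSE), S against M 0 with 828 unadjusted in ESE and the MSE against ESE interaction 61. ESR1 then stood at 0.03 in E against N and FOXO1 at -0.27 in S against M. With quantile normalization applied again they were E against O 222 (5 and 16 in PE and MSE), the ESE against PE interaction 0 with 1600 unadjusted and the MSE against ESE interaction 5. A fold change threshold gave E against O 208 and S against M 3635. An additive model gave E against O 884. Leaving out the 3 arrays outside their title order gave E against N 1881 in ESE and E against O 16 in MSE. The MSE against ESE interaction was 14.

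Of 600 list tests, camera called 145 with the preset correlation and 2 with an estimated one. The classifier of E against N moved from 0.944 to 0.959 with 20 genes, 0.931 with 500 and 0.8 with covariates. It gave 0.605 when centred (permutation p = 0.08), 0.898 within set 1 and 0.923 within set 3. Trained outside these sets it gave 0.338 and 0.472 in them. For E against O it moved from 0.744 to 0.645 with covariates, 0.665 when centred (permutation p = 0.01), 0.69 within set 2 and 0.344 when tested in set 3 (8 and 4 arrays). For O against N it fell from 0.963 to 0.573 with covariates, 0.339 when centred and 0.278 when tested in set 3 (4 and 27 arrays). The stage classifier fell from 0.732 to 0.712 with 500 genes, 0.462 with covariates, 0.347 when centred (shuffled mean 0.441) and 0.46 within set 2. It stood at 0.733 when tested in set 3 (5 and 3 arrays), which does not separate stage from phase. Centring per set removes the difference of groups holding a set alone, as 48 of 75 E arrays do against N. Shuffled labels averaged 0.233 for O against N in place of 0.482, so that area is biased downward. For E against N they averaged 0.495, which does not exclude bias.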

Other observations

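The tests with the array set as a block, those within set 3 and the check of phases centred by set were tests chosen after the data had been seen, and the gene lists were fixed in advance.

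Further genes changed along the cycle in endometriosis. From PE to ESE the ectonucleotidase ENPP3 rose (adjusted p = 4.17e-09; block 4.68 ± 0.64), and CYP26A1, which breaks down retinoic acid, rose by 4.63 ± 0.81 (adjusted p = 3.14e-06; block 4.80 ± 0.80). DOK7, an adaptor of a muscle receptor kinase, fell by 3.44 ± 0.53 (block -3.02 ± 0.45), and FJX1 fell by 3.09 ± 0.42 (block -2.72 ± 0.34). From ESE to MSE the antigen presentation gene HLA-DOB fell by 5.12 ± 0.59 (adjusted p = 3.22e-12) and the calpain CAPN6 fell by 5.05 ± 0.69 (adjusted p = 2.32e-09), at -5.11 ± 0.59 and -4.94 ± 0.68 with the block. Hypoxia and glycolysis genes rose in 10 of 19 cases and fell in 2 from PE to ESE, the same adjusted over the list alone (camera adjusted p = 0.0993; fry adjusted p = 0.00203; adjusted p = 0.994 with an estimated correlation). Cell cycle genes fell in 8 of 38 over that step, also adjusted over the list alone (camera adjusted p = 0.0993; adjusted p = 0.994 with an estimated correlation). In no pathology 0 of them passed in limma, also adjusted over the list alone, with a median of -0.43 (camera adjusted p = 7.45e-05; adjusted p = 0.642 with an estimated correlation).

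CST1, a secreted cystatin, was higher in endometriosis than in no pathology by 2.86 ± 0.52 (adjusted p = 7.83e-07) and in other pathology by 4.09 ± 0.61 (adjusted p = 1.18e-08), but not with the set as a block (adjusted p = 0.207 and 0.0626). SRGAP2C was lower in endometriosis (adjusted p = 1.6e-13), with the block (adjusted p = 0.00318) and within set 3 (-1.56, adjusted p = 0.0011).

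In endometriosis against no pathology, members of several cell type lists passed over all genes. Of all 13705 genes 11010 passed, 4663 higher and 6347 lower. Counts near these shares, here and in the next paragraph, do not set a list apart. The lists that follow gave the same counts adjusted over the list alone, except where noted. T cell markers were higher in 8 of 11 cases (camera adjusted p = 0.0229), smooth muscle markers in 11 of 19 and lower in 3 (camera adjusted p = 0.0229), macrophage markers in 9 of 16 and lower in 1 (camera adjusted p = 0.0652), and natural killer markers in 6 of 14 and lower in 2 (camera adjusted p = 0.0798). Epithelial markers were higher in 14 of 19 and lower in 5 (camera adjusted p = 0.0798), stromal markers in 10 and 7 of 20 (camera adjusted p = 0.117), developmental homeobox genes in 11 and 5 of 20 (camera adjusted p = 0.119), and B and plasma cell markers in 4 and 2 of 8 (camera adjusted p = 0.209). All 8 of these lists had an adjusted p = 0.739 with an estimated correlation. At most 2 members of each of these lists passed over all genes with the set as a block. Smooth muscle and natural killer markers had a camera adjusted p = 3.1e-05 and 2.36e-05 with the block, each with an adjusted p = 0.544 with an estimated correlation. Of the natural killer markers 5 were higher adjusted over the list alone with the block, among them none that passed over all genes.

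Interferon response genes were lower in 15 of 23 cases and higher in 4 (camera adjusted p = 0.209; fry adjusted p = 0.000545; adjusted p = 0.819 with an estimated correlation), and 1 was lower with the block. Estrogen response genes were lower in 12 of 21 and higher in 5 (camera adjusted p = 0.551; adjusted p = 0.823 with an estimated correlation), steroid receptor and enzyme genes in 11 and 5 of 21 (camera adjusted p = 0.601; adjusted p = 0.819 with an estimated correlation), and Wnt pathway genes in 12 and 4 of 25 (camera adjusted p = 0.671; adjusted p = 0.885 with an estimated correlation). Hypoxia and glycolysis genes were lower in 8 of 19 and higher in 3, 2 of these adjusted over the list alone (camera adjusted p = 0.712; adjusted p = 0.906 with an estimated correlation). Inflammatory cytokine genes were higher in 9 of 27 and lower in 6, 5 of these adjusted over the list alone (camera adjusted p = 0.209; adjusted p = 0.819 with an estimated correlation). Matrix remodelling genes were higher in 7 of 28 and lower in 6, 5 of these adjusted over the list alone. Their median was -0.14 and their mean -0.18, while camera gave an upward direction (adjusted p = 0.643; adjusted p = 0.9 with an estimated correlation).

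Cell cycle genes were lower in other pathology than in no pathology in 22 of 38 cases and higher in 5, the same adjusted over the list alone (camera adjusted p = 0.0852; adjusted p = 0.871 with an estimated correlation), and 3 were lower with the block. Between endometriosis and other pathology few list members passed. Secretory list genes (0 of 37, median 0.18, camera adjusted p = 9.79e-05), T cell markers (0 of 11, 0.11, 0.00881), mast and neutrophil markers (0 of 12, 0.26, 0.00384), blood markers (0 of 6, 0.21, 0.0119), cervical squamous markers (0 of 5, 0.33, 0.00595) and ribosomal protein genes (1 of 19, 0.05, 0.000132) were called upward by camera, each with an adjusted p = 0.416 with an estimated correlation. These counts were the same adjusted over the list alone. Adjusted over the list alone, limma gave 0, 5, 3, 2, 3 and 6 with the set as a block. Endothelial markers were lower in 1 of 18, 2 adjusted over the list alone (camera adjusted p = 0.0344; adjusted p = 0.648 with an estimated correlation).

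As a check for mixed-up samples, each array was set against the phase means of the arrays outside its fold on 100 genes, with values centred per array set, and 27 of 144 arrays lay nearest another phase than the one given: 8 of 64 in PE, 11 of 30 in ESE and 8 of 50 in MSE. Of these, 2 were PE arrays nearest MSE or the reverse. The sets differed in their mix of PE, ESE and MSE arrays, with 8, 5 and 13 in set 1 and 21, 11 and 7 in set 3. Centring per set then shifts arrays differently by set, so the 27 do not show wrong labels. The 3 hidden factors held 38%, 10.3% and 7.6% of the residual variance, of which array set accounted for 40.6%, 58.1% and 0.4%. The 2 LSE arrays and the 2 with no phase entered no comparison.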
